A study of Arabidopsis thaliana with 12 samples.

How the data were processed

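RNA from shoots of Col wild type and clf seedlings, on sufficient or deficient iron, was sequenced from TruSeq stranded mRNA libraries, per the labels' protocols. The 12 libraries form 4 groups of 3, assigned from the titles and growth descriptions. Reads were aligned with TopHat2 to the TAIR10 genome, per the submitters' processing notes, which give no version. The counting tool, annotation version, strand setting and clf allele are not given in the sources used here. The deposited counts are whole numbers per gene and library with no normalization, as read from the values. The deposited FPKM values are counts per kilobase and library total made by the authors: for 12911 of 12911 genes with over 50 counts in every library, count over FPKM was proportional to the library total within a relative 1e-09. Gene names and coordinates come from the TAIR10.1 gene table, in which 31912 of the 32678 identifiers were found and 766 were not. A single text cell in an unnamed last column of the count table was not used.

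Counts per library summed to between 16092041 and 29400813, and 8107 identifiers had 0 counts in every library. The 10 most abundant genes took 9.72% to 16.7% of counts, ribosomal RNA genes 0.0155% to 0.936% and plastid and mitochondrial genes 0.0469% to 0.230%. Replicates were checked for duplication: the chi-square per gene between pairs within a group was 5.46 to 101 and the Spearman correlation 0.936 to 0.992. Reads were counted without molecular identifiers, so the intervals and floors below cover counting error only.

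The groups, tests, gene lists, rule for naming genes and alternatives were fixed before the data were examined. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which kept 19148 of 32678. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 under R 4.3.3 with glmQLFit on all 12 libraries in 4 groups (8 residual degrees of freedom, common biological coefficient of variation 0.308). Comparisons were tested with glmQLFTest, the quasi-likelihood F test, and genes called at a Benjamini-Hochberg adjusted p under 0.05, written as edgeR adjusted p. The comparisons were deficient against sufficient iron in each genotype, clf against wild type at each iron level, and the interaction (iron response in clf minus that in wild type). The mean iron effect and the mean clf effect were fitted for the overlap of both. CPM values use TMM-scaled library sizes, with group means and SD over 3 libraries. Log2 fold changes are those of edgeR, and SE is their standard error from the same fit.

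For a group at 0 counts the fold is given as a lower bound with 3 counts over the group in its place. For a group with 1 to 3 counts the ratio is given with its exact 95% interval for counts. Medians of lists with a member at 0 counts were also taken with that member at its bound.

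The 25 gene lists cover iron signalling, iron acquisition, iron transport, iron storage and iron-containing proteins, iron-sulfur assembly, copper, zinc, photosystems, chlorophyll and heme, Polycomb and trithorax proteins, floral MADS proteins, flowering time, KNOX and meristem, seed maturation, anther and carpel, root, leaf, guard cells, phloem, xylem, defence, oxidative stress, the circadian clock, anthocyanin and flavonoids, and aliphatic glucosinolates. Of 390 members, 7 were dropped because the reference gives the locus another symbol. These were SUFA, SUFB, SUFC, SUFD and GRXS14 of iron-sulfur assembly, DVR of chlorophyll and heme, and IPMDH1 of aliphatic glucosinolates. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the lists of a comparison and written as camera adjusted p. Camera with an estimated correlation and fry were run beside it. Camera was not run on lists with fewer than 3 measured genes. Calls over all genes and calls adjusted over the list alone were counted for each list.

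CLF and SWN were named in every library. In each comparison the 10 largest increases and 10 largest decreases were named among called genes with at least 5 CPM in the higher group and no overlap of the groups' values, without organelle and ribosomal RNA genes. For the interaction the 10 genes with the smallest adjusted p were named. In each list up to 4 called members with the smallest adjusted p could be named, and any member of the 4 lists for iron signalling, acquisition, transport and storage whether called or not. Genes named outside this rule are said to be chosen after their values were seen.

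Overlaps of calls were set against the number for independent lists, and comparisons that share libraries also against 20 simulations of groups without effects. On simulated data with 200 genes changed, 84% of 4-fold increases and 78% of 4-fold decreases were recovered for the iron effect in wild type, 34% and 18% at 2-fold, with 3 false calls among 18919 genes. The iron effect in clf gave 78% and 76% at 4-fold, 34% and 30% at 2-fold (3 false calls among 18928). The clf effect gave 84% and 74%, 26% and 40% on sufficient iron (9 among 18939), and 82% and 74%, 26% and 18% on deficient iron (4 among 18935). The interaction gave 62% and 52% at 4-fold, 2% and 2% at 2-fold, with 0 false calls among 18935 genes. Genes were drawn independently, without the variation that genes share within groups in the real libraries, so these figures may differ in the real data.

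Alternatives fixed beforehand were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, a strict filter (1 CPM in 6 libraries), the replicate number as a block, only the groups compared, a log2 fold change of at least 1, limma on log2 FPKM (0.5 added, at least 1 in 3 libraries), camera with an estimated correlation, and each library left out in turn. Alternatives added after seeing the data were a term for the 4 libraries that stood apart, leaving these out, and thinning every library to the smallest total. The 4 libraries were picked for lying farthest out within their groups. With the term or without these libraries, the spread tested against shrinks through that choice alone. More calls and smaller p-values in those fits can come from it. Labels were also exchanged in other splits of the libraries.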

Results

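RNA was sequenced from shoots of Arabidopsis thaliana seedlings of the Col wild type and of clf, a mutant in CURLY LEAF (CLF), which encodes a histone methyltransferase of Polycomb repressive complex 2. The series asks how this repressive complex bears on iron homeostasis genes in shoots. Seedlings grew for 12 days on B5 medium and then for 3 days on medium with sufficient or deficient iron, at 22 °C with 16 h of light and 8 h of dark. The 4 groups held 3 libraries each. Gene counts per library summed to 19591512, 16092041 and 17183333 in wild type on sufficient iron (replicates 1 to 3) and to 25949302, 23765574 and 26830488 in wild type on deficient iron. They summed to 18135767, 17524002 and 20706803 in clf on sufficient iron and to 21297005, 28350032 and 29400813 in clf on deficient iron, so all 6 deficient libraries were deeper than all 6 sufficient ones. The source name, titles and design text call the tissue shoot, while a second tissue label and the extraction text call it root. Genes of photosynthesis were the most abundant in every library: LHCB1.3, a light-harvesting protein gene, or RCA, Rubisco activase, took the most counts. No source used here says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

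In each group 1 library stood apart from the other 2: replicate 3 of wild type on sufficient iron, replicate 2 of wild type on deficient iron, and replicate 3 of clf in both conditions. TOC1, an evening gene of the circadian clock, was at 59.6, 33.2, 34.9 and 30.2 CPM (counts scaled to library size) in those 4 libraries and between 9.44 and 13.0 CPM in the other 8. LHY, a morning gene of the clock, was at 65.2, 231, 110 and 163 CPM in the same 4 libraries and between 204 and 443 CPM in the other 8. PRR5, GI, FKF1 and CCA1 also had their extreme value in that library in all 4 groups. These clock genes were chosen after their values were seen.

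**Figure D1:**
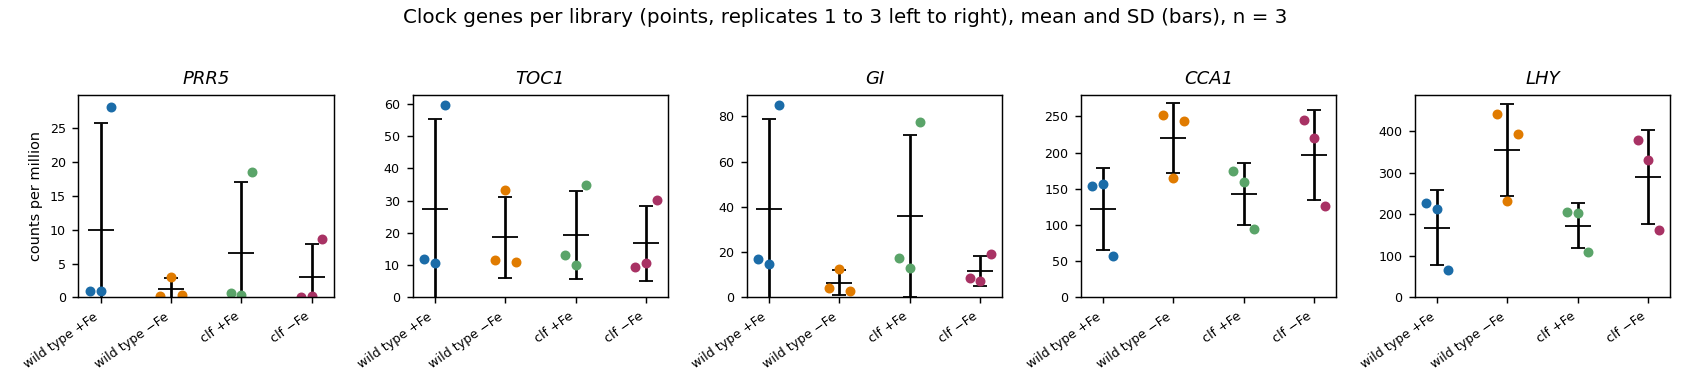
The vertical axis of each panel gives CPM of a clock gene, with points for the 3 replicates of each group in order and bars for the group mean and SD. The library that stood apart had the highest PRR5, TOC1 and GI and the lowest CCA1 and LHY of its group, for example 59.6 CPM of TOC1 in wild type on sufficient iron against 11.8 and 10.6 CPM.

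CLF (AT2G23380, chromosome 2, 9955092 to 9960386 in the TAIR10.1 annotation) carried fewer reads in every clf library than in any wild-type library. Its values were 13.1, 15.8 and 14.2 CPM in wild type on sufficient iron and 15.2, 14.6 and 17.1 CPM on deficient iron. In clf they were 4.65, 3.09 and 5.35 CPM on sufficient iron and 3.28, 4.24 and 5.40 CPM on deficient iron. The log2 fold change in clf was -1.72 (SE 0.22, adjusted p 0.0024) on sufficient and -1.86 (SE 0.22, adjusted p 0.0013) on deficient iron by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, which gives all adjusted p-values of single genes here. SWN (AT4G02020, chromosome 4), a second methyltransferase of the complex, had 34.98, 30.3 and 31.6 CPM in wild type on sufficient iron and 34.3, 28.3 and 31.7 CPM on deficient iron. In clf it had 39.7, 38.0 and 32.3 CPM on sufficient iron and 33.0, 33.9 and 27.9 CPM on deficient iron. SWN passed the test in none of the comparisons.

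The comparison of deficient with sufficient iron in wild type asks which shoot genes respond to 3 days of iron deficiency. Some transcription factor genes of the iron deficiency response rose from near absence, among them bHLH38 and bHLH39. bHLH38 (AT3G56970) went from 0.162 ± 0.225 to 372 ± 62.1 CPM (mean ± SD, n = 3). Its log2 fold change was 11.22 (SE 0.58, edgeR adjusted p 2.7e-06). Its neighbour bHLH39 (AT3G56980; chromosome 3, 21084035 to 21085245 and 21086390 to 21087710 in TAIR10.1) went from 0.299 ± 0.0441 to 259 ± 30.8 CPM. Among genes that fell, FER1 (AT5G01600), for the iron storage protein ferritin, went from 89.0 ± 46.7 to 4.94 ± 0.361 CPM (log2 fold change -4.17, SE 0.46, edgeR adjusted p 0.00045). HEMA1 (AT1G58290), for the glutamyl-tRNA reductase that opens chlorophyll and heme synthesis, went from 1482 ± 6.93 to 94.7 ± 32.7 CPM (log2 fold change -3.97, SE 0.33, edgeR adjusted p 5.8e-05). In all, 882 of 19148 tested genes were higher and 865 lower on deficient iron, of which 353 and 309 changed by at least 2-fold.

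Of 18 measured genes of iron signalling, 12 rose and 1 fell (14 and 1 adjusted over the list alone). The list as a whole moved up, with camera adjusted p 2.8e-17 and an adjusted p of 0.0013 with an estimated correlation. Besides bHLH38 and bHLH39 these included bHLH100, with 2 counts in the sufficient libraries and a ratio with a counting interval of 1984 to 59178. IMA1 and IMA2, neighbouring genes of iron-signalling peptides, had log2 fold changes of 10.40 (SE 0.62) and 9.31 (SE 0.59). BTS, a ubiquitin ligase that holds back the response, rose from 102 ± 4.03 to 1188 ± 154 CPM (log2 fold change 3.55, SE 0.16, edgeR adjusted p 1.4e-06). PYE, a transcription factor that represses transport genes, rose by 2.79 (SE 0.32) on the log2 scale, and bHLH121 was the member that fell (log2 fold change -0.53, edgeR adjusted p 0.039). FIT, the regulator of iron uptake in roots, was at 0.338 ± 0.201 CPM on sufficient and 1.503 ± 0.921 CPM on deficient iron and did not pass (edgeR adjusted p 0.059).

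Of 19 measured genes of iron transport, 7 rose and 3 fell (8 and 4 over all members when adjusted over the list alone; camera adjusted p 0.0041, adjusted p = 0.055 with an estimated correlation). OPT3, which loads iron into the phloem, rose from 110 ± 13.9 to 1161 ± 82.7 CPM (log2 fold change 3.40, SE 0.13, edgeR adjusted p 3.4e-07). FRO3, a mitochondrial ferric reductase, rose by 4.30 (SE 0.22) and NRAMP4, a vacuolar iron exporter, by 2.83 (SE 0.13) on the log2 scale. The nicotianamine synthase genes went both ways: NAS4 rose by 5.03 (SE 0.32) and NAS3 fell by 3.45 (SE 0.47) on the log2 scale. Of 10 measured genes of iron storage and iron-containing proteins, 7 fell (8 adjusted over the list alone; camera adjusted p 8.1e-10, adjusted p = 0.018 with an estimated correlation). NEET (AT5G51720), an iron-sulfur protein gene, fell by 5.54 (SE 0.35), FER4 by 3.41 (SE 0.31) and FSD1, an iron superoxide dismutase, by 2.71 (SE 0.21), from 887 ± 9.95 to 136 ± 19.4 CPM.

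Of 13 measured genes of iron acquisition, best known from the root surface, 7 rose (8 adjusted over the list alone; camera adjusted p 4.6e-06, adjusted p = 0.13 with an estimated correlation). CYP82C4, for a hydroxylase of coumarin synthesis, went from 2.37 ± 2.25 to 32.9 ± 13.9 CPM (log2 fold change 3.81, SE 0.73, edgeR adjusted p 0.0099). IRT1, the iron uptake transporter, went from 4.98 ± 3.90 to 31.7 ± 10.8 CPM (edgeR adjusted p 0.041) and FRO2, the root surface ferric reductase, from 6.43 ± 4.55 to 34.8 ± 7.22 CPM (edgeR adjusted p 0.036). The calls of IRT1 and FRO2 were lost when 8 and 7 of the 12 libraries were left out in turn, with edgeR adjusted p of up to 0.12 for each, without replicate 2 of wild type on sufficient iron. None of 16 measured root markers passed in this comparison by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2; median log2 fold change 0.35, camera adjusted p 0.49). Leaf markers were lower as a list (camera adjusted p 0.012, adjusted p = 0.45 with an estimated correlation), with 1 of 10 called (3 adjusted over the list alone), CA1, a carbonic anhydrase (log2 fold change -0.59, SE 0.12).

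**Figure D2:**
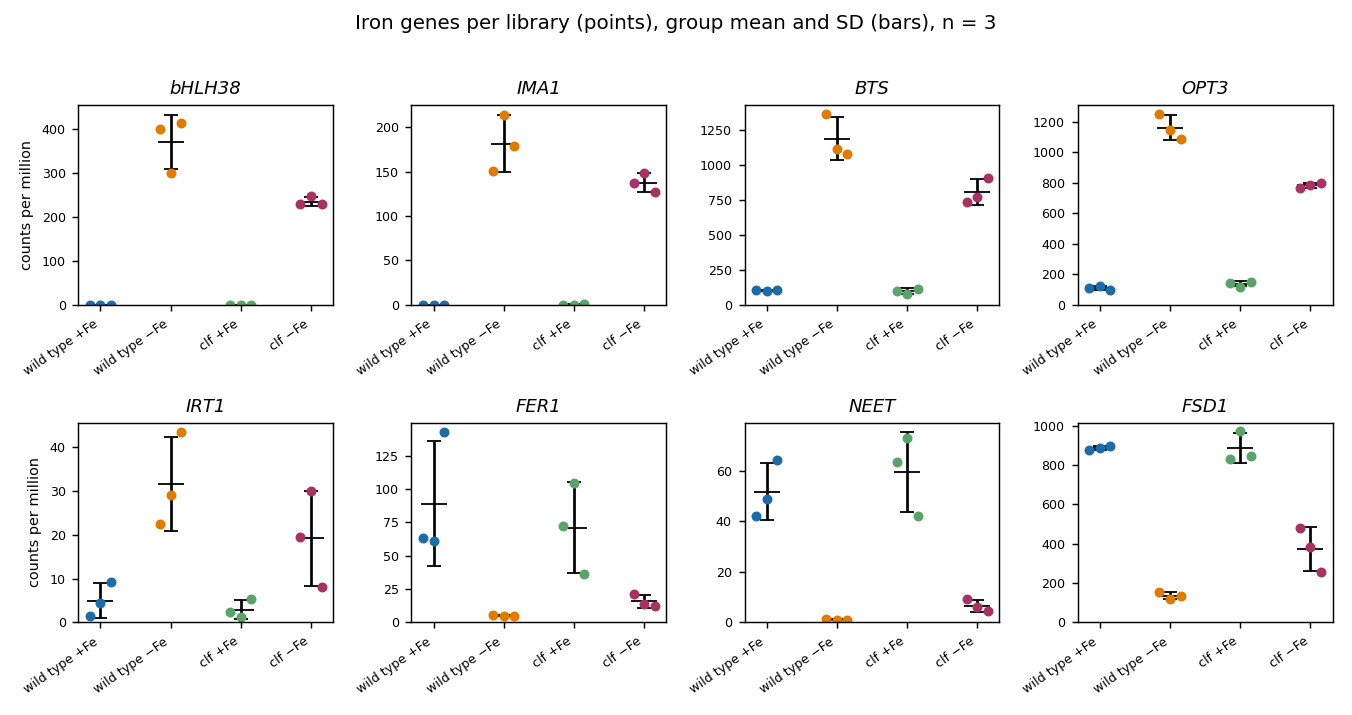
The vertical axis of each panel gives CPM of an iron gene, from 0, with points for the 3 libraries of each of the 4 groups and bars for the group mean and SD. bHLH38 and OPT3 were at 372 and 1161 CPM in wild type on deficient iron and at 235 and 783 CPM in clf, and FSD1 was at 136 CPM in wild type and 372 CPM in clf.

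Photosystem genes fell together: 34 of 39 were lower (37 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.83 (camera adjusted p 8.5e-28, adjusted p = 0.093 with an estimated correlation). The smallest p-values were those of PSAF and PSAD2 of photosystem I and FD2, the main leaf ferredoxin, which went from 2228 ± 320 to 439 ± 51.2 CPM (log2 fold change -2.34, SE 0.20, edgeR adjusted p 9.0e-05). Of 22 genes of chlorophyll and heme synthesis, 8 fell (10 adjusted over the list alone; camera adjusted p 3.7e-08, adjusted p = 0.0029 with an estimated correlation), among them PORA, a protochlorophyllide reductase, by 2.35 (SE 0.26) on the log2 scale. Leaf markers moved with both groups, as given above. Of 13 genes of aliphatic glucosinolate synthesis, 8 rose (10 adjusted over the list alone; camera adjusted p 3.5e-07, adjusted p = 0.093 with an estimated correlation). Among them were CYP79F1, which makes the aldoxime precursors (log2 fold change 1.02, SE 0.16), and CYP83A1 (0.99, SE 0.15). Of 10 anthocyanin and flavonoid genes, FLS1 and AT1G56650, the MYB regulator PAP1, passed (8 adjusted over the list alone; camera adjusted p 0.00020, adjusted p = 0.30 with an estimated correlation). Their calls were lost in 4 and 7 of the 12 fits with a library left out, with edgeR adjusted p of up to 0.10 and 0.12.

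In the oxidative stress list 4 of 15 fell (4 adjusted over the list alone; camera adjusted p 0.077). These were the ascorbate peroxidase genes APX1 (log2 fold change -1.93, SE 0.24) and SAPX (-3.06, SE 0.29) and the catalase genes CAT1 (-3.09, SE 0.56) and AT1G20620 (-2.86, SE 0.37). In the copper list of 14, the copper transporter COPT2 rose and CSD2, CCS and PETE2 fell (1 and 4 adjusted over the list alone; camera adjusted p 0.49). CYP71A13 and WRKY54 rose in the defence list of 17 (2 adjusted over the list alone; camera adjusted p 0.12). Single members moved in 4 further lists: PRR9 fell among 20 clock genes, SVP among 9 flowering-time genes and AGL17 among 14 floral MADS genes (8 counts against 1, ratio interval 1.83 to 606), and VRN5 rose among 16 Polycomb and trithorax genes. Adjusted over each list alone, 1, 0, 0 and 1 rose and 2, 1, 1 and 1 fell, and the camera adjusted p lay between 0.26 and 0.98. With a library left out, VRN5 lost its call in 11 of the 12 fits (edgeR adjusted p up to 0.14), AGL17 and bHLH121 in 9 (0.13 each), PETE2 in 4 (0.066), CA1 and CCS in 2 (0.060 and 0.061) and CSD2 and WRKY54 in 1 (0.056 and 0.053). By edgeR 0 members passed in the lists for iron-sulfur assembly (10 measured, 3 at an unadjusted p under 0.05, 1 by DESeq2), zinc (10, 1 and 0) and guard cells (8, 1 and 0). The same held for phloem (6, 0 and 0), xylem (5, 1 and 0) and the meristem (3, 0 and 0), with camera adjusted p of 0.26 or more. The iron-sulfur result leaves out SUFA, SUFB, SUFC, SUFD and GRXS14, which were dropped for their symbols and not tested in that list. Anther and carpel genes (2 measured, 1 at an unadjusted p under 0.05, 1 by DESeq2) and seed maturation genes (1 measured, 0 and 0) were too few for camera, and 0 passed by edgeR.

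Beyond the lists, the largest increases included AT4G36700, a cupin gene (log2 fold change 11.89, SE 0.63) and AT1G13608, a defensin-like gene (at least 151-fold, with a floor of 3 counts over a group at 0 counts). SESA5, a seed storage albumin, had 0 counts in the sufficient libraries and 16.6 ± 2.14 CPM on deficient iron (at least 260-fold higher). PYL3, an abscisic acid receptor gene, and AT1G47405, annotated as a pseudogene beside IMA1, were at least 100.9-fold and 83.2-fold higher. The largest decreases included AT3G49160, a pyruvate kinase family gene (log2 fold change -6.41, SE 0.63), AT5G59400, a gene like PGR5 (-4.53, SE 0.36), and AT3G43850 (-3.38, SE 0.29). Others were AT3G43670, a copper amine oxidase gene (-3.22, SE 0.33), and ASN1, an asparagine synthetase, which went from 979 ± 375 to 82.7 ± 35.3 CPM. All 20 genes of largest change kept their call when any of the 12 libraries was left out. The numbers of higher and lower genes went to 476 and 575, 399 and 517, 372 and 476, and 443 and 507 without replicates 1 and 2 of sufficient and 1 and 3 of deficient wild type. They went to 2165 and 1950 with a term for the 4 libraries that stood apart. Among calls 50.5% were higher with TMM scaling, but 85.1% (2633 higher, 462 lower) with limma on the deposited FPKM, where the median log2 fold change of all genes was 0.22 in place of 0.01.

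The same comparison in clf asks how the mutant shoot responds to iron deficiency. The same regulators led: bHLH38 went from 0.234 ± 0.108 to 235 ± 10.3 CPM (log2 fold change 9.93, SE 0.55, edgeR adjusted p 6.5e-06). The genes bHLH100 (9.52, SE 0.45), bHLH39 (8.71, SE 0.55), IMA2 (8.63, SE 0.57), IMA1 (8.42, SE 0.54) and bHLH101 (6.98, SE 0.39) were also among the 10 largest increases. Others were the defensin-like genes AT1G13608 (at least 146-fold) and AT1G13609 (log2 fold change 8.68, SE 0.72), AT2G14247 (7.94, SE 0.50) and the cupin gene AT4G36700 (7.45, SE 0.50). NEET fell by 3.20 (SE 0.31), HEMA1 by 2.42 (SE 0.31) and FER4 by 2.07 (SE 0.29) on the log2 scale, as did the copper/zinc superoxide dismutase genes CSD1 (-2.56, SE 0.36) and CSD2 (-2.93, SE 0.48). AT2G36885, annotated as a translation initiation factor, fell by 4.17 (SE 0.55) on the log2 scale. In all, 144 genes were higher and 147 lower, of which 88 and 69 changed by at least 2-fold.

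Of 18 measured iron signalling genes, 10 rose (12 adjusted over the list alone; camera adjusted p 3.7e-23, adjusted p 0.00043 with an estimated correlation). Of 19 transport genes, 5 rose (7 rose and 5 fell adjusted over the list alone; camera adjusted p 0.0045, adjusted p = 0.061 with an estimated correlation). ZIF1, a vacuolar nicotianamine transporter, rose by 2.63 (SE 0.09) and OPT3 by 2.51 (SE 0.13) on the log2 scale. Of 10 genes of iron storage and iron-containing proteins, 6 fell (7 adjusted over the list alone, camera adjusted p 7.1e-08, adjusted p = 0.035 with an estimated correlation). Of 13 acquisition genes, CYP82C4 and FRO2 rose (7 adjusted over the list alone; camera adjusted p 3.9e-06, adjusted p = 0.13 with an estimated correlation). IRT1 was at 2.90 ± 2.12 and 19.1 ± 10.9 CPM with an edgeR adjusted p of 0.098. Of 39 photosystem genes, 20 fell (35 adjusted over the list alone; median log2 fold change -0.66, camera adjusted p 2.6e-30, adjusted p = 0.083 with an estimated correlation). HEMA1, PORA and CHLM fell in the chlorophyll and heme list of 22 (6 adjusted over the list alone; camera adjusted p 6.4e-07, adjusted p = 0.0054 with an estimated correlation). In the glucosinolate list FMOGS-OX1 rose (8 of 13 adjusted over the list alone; camera adjusted p 2.6e-06, adjusted p = 0.12 with an estimated correlation).

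Markers of other tissues moved with these groups in clf. Root markers were lower as a list on deficient iron (median log2 fold change -1.07, camera adjusted p 0.00045, adjusted p = 0.39 with an estimated correlation). By edgeR 0 of 16 were called (6 at an unadjusted p under 0.05, 4 by DESeq2, 5 lower adjusted over the list alone). Leaf markers (camera adjusted p 0.00012, adjusted p = 0.19 with an estimated correlation) and xylem genes (0.024 and 0.19) were lower as lists too, CA1 being the member called (log2 fold change -0.94, SE 0.12). Calls were lost in at least 1 of the 12 fits with a library left out for AT3G49160, CSD2, IRT3, FER1 and AT5G59400 of the 20 genes of largest change. For FER1 (log2 fold change -2.18, SE 0.42) the edgeR adjusted p reached 0.14 without replicate 2 of clf on deficient iron. FMOGS-OX1, FRO2, CYP82C4 and CHLM lost their calls in 10, 9, 7 and 6 of the 12 fits, with edgeR adjusted p of up to 0.18, 0.14, 0.16 and 0.12. The numbers higher and lower were 67 and 66, 46 and 44, and 54 and 65 without replicates 1, 2 and 3 of sufficient clf. They were 60 and 73, 49 and 46, and 265 and 188 without replicates 1, 2 and 3 of deficient clf, and 938 and 803 with a term for the 4 libraries that stood apart. With limma on FPKM 79.7% of calls were higher (472 higher, 120 lower) against 49.5% with TMM, and the median log2 fold change of all genes was 0.14 in place of -0.02.

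Of the 291 genes called in clf, 240 (82.5%) were also called in wild type, each in the same direction, where 13.3 would be shared by independent lists. This number was 78 without replicate 2 of deficient clf and 1209 with a term for the 4 libraries that stood apart. The log2 fold changes of all 19148 genes correlated between genotypes with r = 0.57 (across genes, which are not independent replicates). Over the 2608 genes called for the mean iron effect of both genotypes, a set defined on these libraries, the median change in the direction of that effect was 0.68 in wild type and 0.47 in clf on the log2 scale. The signed median difference was -0.22 and 75.9% of these genes changed less in clf (fry p 0.0113, a test chosen after the values were seen).

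**Figure D3:**
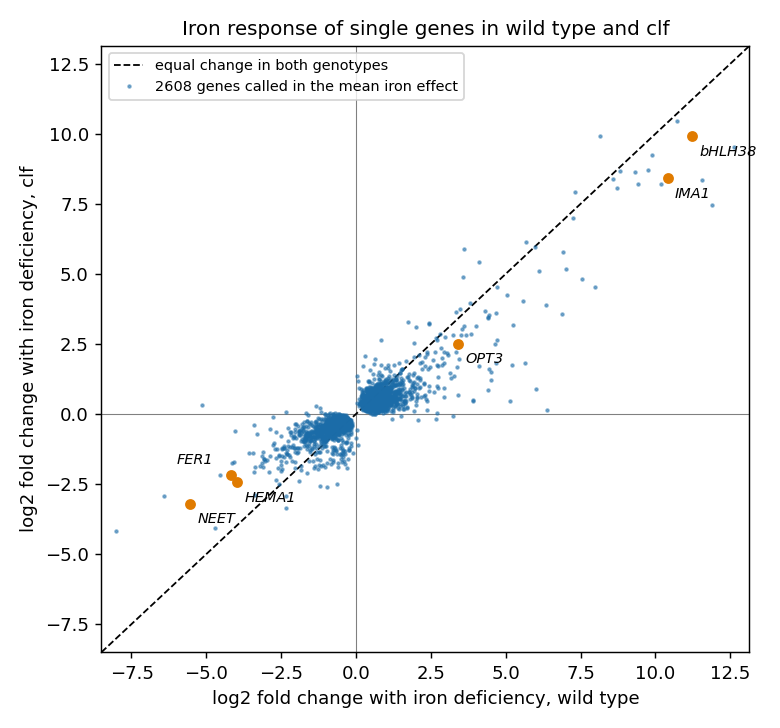
Each point is 1 of the 2608 genes called in the mean iron effect, with its log2 fold change on deficient against sufficient iron in wild type on the horizontal axis and in clf on the vertical axis, and the dashed line marks equal change. Most points lie between the line and 0 in clf, with 75.9% of the genes changing less in clf and bHLH38 at 11.22 in wild type and 9.93 in clf.

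The comparison of clf with wild type on sufficient iron asks what loss of CLF does to shoot expression when iron is not limiting. Genes of flower identity that were near absent in wild type were expressed in clf. AG (AT4G18960, chromosome 4, 10382856 to 10388539), which specifies stamens and carpels, went from 0.147 ± 0.0164 to 34.8 ± 3.63 CPM (log2 fold change 7.82, SE 0.51, edgeR adjusted p 3.4e-05). SEP3 (AT1G24260, chromosome 1, 8593536 to 8596123), a cofactor of the floral MADS proteins, went from 1.04 ± 0.385 to 102 ± 10.02 CPM (log2 fold change 6.62, SE 0.23, edgeR adjusted p 3.2e-07). FT (AT1G65480), the mobile signal for flowering, had 3 counts in wild type and rose to 10.5 ± 0.685 CPM (counting interval of the ratio 56.4 to 806). In all, 687 genes were higher and 253 lower in clf, of which 479 and 90 changed by at least 2-fold.

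Of 14 measured floral MADS genes, 13 rose (14 adjusted over the list alone; median log2 fold change 3.49, camera adjusted p 8.0e-24, adjusted p 0.0018 with an estimated correlation). Besides AG and SEP3 these included AP3, with a ratio interval of 22.6 to 5089 from 1 count in wild type, and SHP2, with 23.0 to 700 from 2 counts. STK, for ovule identity, was at least 19.8-fold higher, with 0 counts in wild type, and the list median with STK at this bound was unchanged at 3.49. In the flowering-time list of 9, FT, SOC1 (log2 fold change 0.78, SE 0.15) and the flowering repressor FLC (2.01, SE 0.35) rose. SVP (-0.86, SE 0.12) and MAF5 (-0.76, SE 0.16) fell (3 higher and 2 lower adjusted over the list alone; camera adjusted p 0.28). In the Polycomb and trithorax list of 16, MEA, a methyltransferase gene of the seed form of the complex, rose from 1 count in wild type (ratio interval 16.5 to 3732) and CLF fell (1 and 1 adjusted over the list alone; camera adjusted p 0.69). KNOX and meristem genes (3 measured, camera adjusted p 0.32) held 0 called members by edgeR (0 at an unadjusted p under 0.05, 0 by DESeq2).

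The other large increases were AT5G60140, a B3 transcription factor gene (at least 79.9-fold), the homeobox gene HB40 (ratio interval 133 to 29449, from 1 count) and SWEET10, a sugar transporter (log2 fold change 7.66, SE 0.49). Others were SCPL43, a carboxypeptidase (62.0 to 1863, from 2 counts), AO4, an aldehyde oxidase (43.4 to 9669, from 1 count), LTP4, a lipid transfer protein (71.7 to 1023, from 3 counts), and AT1G03710, a cystatin family gene (6.63, SE 0.58). The largest decreases were AT3G16670, of the pollen Ole e 1 allergen family, from 79.1 ± 25.9 to 0.927 ± 1.02 CPM (log2 fold change -6.38, SE 0.91). Next came AT3G05730, a defensin-like gene, from 232 ± 50 to 14.5 ± 6.53 CPM (-4.004, SE 0.36). AT3G16660, the next family member on chromosome 3, was lower too (-2.24, SE 0.32), as were the receptor kinase CRK12 (-2.86, SE 0.34) and the adjacent AT5G34790 (-3.14, SE 0.40) and AT5G34800 (-3.02, SE 0.40), both annotated as pseudogenes. Further decreases were AT2G43590, a chitinase gene (-2.33, SE 0.47), AT5G02540 (-2.18, SE 0.40), AT1G75490, a DNA-binding protein gene (-2.17, SE 0.38), and AT2G47485 (-2.06, SE 0.31).

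Iron genes called between the genotypes on sufficient iron were in the transport (4 of 19) and acquisition (1 of 13) lists. Over all genes 940 of 19148 were called. By edgeR 0 of 18 signalling genes passed (2 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p 0.78) and 0 of 10 storage genes (1 and 0; camera adjusted p 0.87). In the transport list of 19, FRO7, a chloroplast ferric reductase (log2 fold change 1.42, SE 0.27), YSL1 (1.17, SE 0.27) and NAS1 (1.103, SE 0.27) rose. So did NRAMP3, a vacuolar iron exporter (0.70, SE 0.12; 4 adjusted over the list alone; camera adjusted p 0.089). NRAMP1, a metal uptake transporter in the acquisition list, rose from 17.6 ± 3.43 to 39.0 ± 5.80 CPM (log2 fold change 1.15, SE 0.17, edgeR adjusted p 0.0045). The calls of NAS1, YSL1 and FRO7 were lost in 8, 6 and 3 of the 12 fits with a library left out. Their edgeR adjusted p rose to 0.15 for NAS1 without replicate 1 and to 0.13 for YSL1 and 0.062 for FRO7 without replicate 2 of sufficient clf.

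Chlorophyll and heme genes were lower in clf as a list (median log2 fold change -0.41, camera adjusted p 1.8e-06, adjusted p 0.0064 with an estimated correlation), with CHLI1, HEME2 and CHLM called of 22 (8 adjusted over the list alone). Photosystem genes were lower as a list (median -0.33, camera adjusted p 8.0e-10, adjusted p = 0.53 with an estimated correlation) with 0 of 39 called by edgeR (19 at an unadjusted p under 0.05, 10 by DESeq2). Among glucosinolate genes CYP79F1, CYP83A1 and SOT18 rose and MAM3 fell (6 and 1 of 13 adjusted over the list alone; camera adjusted p 0.0029, adjusted p = 0.51 with an estimated correlation). Anthocyanin genes were higher as a list (camera adjusted p 0.041, adjusted p = 0.70 with an estimated correlation), with 0 of 10 called by edgeR (5 at an unadjusted p under 0.05, 2 by DESeq2). PBS3, of salicylic acid synthesis, rose by 1.98 (SE 0.28) on the log2 scale (1 higher and 1 lower of 17 defence genes adjusted over the list alone). SEOR1 fell by 0.83 (SE 0.20) among 6 phloem genes (1 adjusted over the list alone). Root and leaf markers had median log2 fold changes of 0.50 and 0.01 (camera adjusted p 0.63 and 0.98).

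Of the 20 genes of largest change, LTP4, AT2G43590 and AT5G02540 lost their call with some library left out. So did CHLM and SEOR1 in 9 of the 12 fits (edgeR adjusted p up to 0.13 and 0.12), HEME2 in 7 (0.14), MAM3 in 5 (0.12), SOT18 in 4 (0.11) and CHLI1 and SOC1 in 1 (0.054 and 0.065). The numbers higher and lower went to 382 and 121, and 344 and 101, without replicates 1 and 2 of sufficient wild type and to 372 and 111, and 307 and 79, without replicates 1 and 2 of sufficient clf. The share of calls that were higher was 73.1%, against 62.9% by DESeq2 (1034 higher, 610 lower) and 87.6% by limma on FPKM (median log2 fold change of all genes 0.11 in place of -0.01). It was 60.0% with a term for the 4 libraries that stood apart (1649 higher, 1099 lower).

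**Figure D4:**
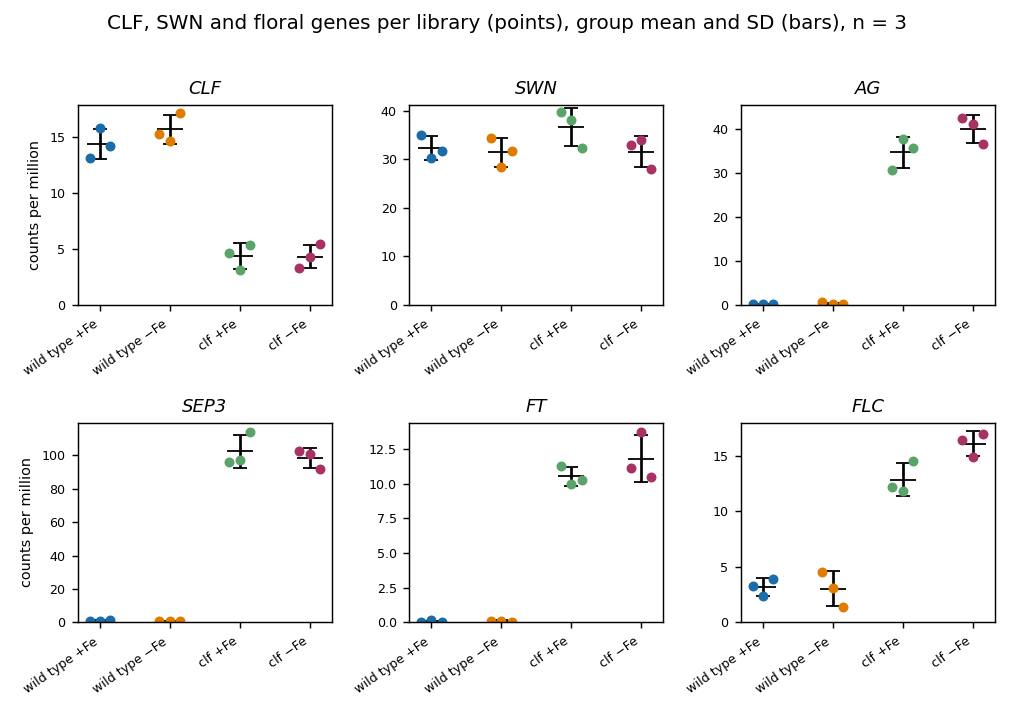
The vertical axis of each panel gives CPM from 0, with points for the 3 libraries of each of the 4 groups and bars for the group mean and SD. CLF was between 3.09 and 5.40 CPM in the 6 clf libraries and between 13.1 and 17.1 CPM in the 6 wild-type libraries, and AG, SEP3, FT and FLC were higher in clf at both iron levels.

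The comparison of clf with wild type on deficient iron asks what loss of CLF does under iron deficiency. AG, SEP3 and FT were again higher. AG was at 0.246 ± 0.266 CPM in wild type and 40.2 ± 3.20 CPM in clf (log2 fold change 7.31, SE 0.46, edgeR adjusted p 1.8e-05). SEP3 was at 0.973 ± 0.0968 and 98.4 ± 5.93 CPM (6.65, SE 0.22) and FT at 0.0894 ± 0.0480 and 11.8 ± 1.70 CPM (6.99, SE 0.41). Of 10 genes of iron storage and iron-containing proteins, 5 were higher in clf. NEET was at 1.102 ± 0.227 CPM in wild type and 6.50 ± 2.45 CPM in clf (log2 fold change 2.55, SE 0.32, edgeR adjusted p 0.0019). FSD1 was at 136 ± 19.4 and 372 ± 113 CPM (1.46, SE 0.20, edgeR adjusted p 0.0026). In all, 768 genes were higher and 471 lower, of which 482 and 163 changed by at least 2-fold.

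In the list of iron storage and iron-containing proteins, the iron-sulfur protein gene NEET and the superoxide dismutase gene FSD1 were higher in clf. So were VTL1 (ratio interval 3.20 to 52.0 from 3 counts in wild type) and the ferritin genes FER1 (log2 fold change 1.66, SE 0.42) and FER4 (1.15, SE 0.30). Adjusted over the list alone, 5 were higher (camera adjusted p 0.0025, adjusted p = 0.28 with an estimated correlation). In the transport list of 19, NAS3 (2.81, SE 0.46), YSL1 (2.55, SE 0.29) and NRAMP3 (0.92, SE 0.12) were higher. OPT3 (-0.57, SE 0.12), NAS4 (-1.10, SE 0.27) and FRO3 (-0.77, SE 0.20) were lower (4 higher and 4 lower adjusted over the list alone; camera adjusted p 0.93). NRAMP1 was higher (1.16, SE 0.17) in the acquisition list of 13 (1 adjusted over the list alone; camera adjusted p 0.087). BTSL1 (AT1G74770), a ubiquitin ligase gene, was lower (-1.24, SE 0.26) in the signalling list of 18 (2 adjusted over the list alone; camera adjusted p 0.086). FER1, FER4, FRO3, NAS4, VTL1, BTSL1 and OPT3 lost their calls in 7, 10, 8, 8, 4, 3 and 3 of the 12 fits with a library left out. Their edgeR adjusted p reached 0.16, 0.17, 0.17, 0.14, 0.078, 0.091 and 0.080, each without replicate 1 of deficient clf.

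Root markers were lower as a list in clf here (median log2 fold change -0.93, camera adjusted p 0.0050, adjusted p = 0.69 with an estimated correlation), with COBL9, a root hair gene, called of 16 (1 adjusted over the list alone). Leaf markers had a median of -0.03 (camera adjusted p 0.38). Of 14 floral MADS genes, 11 rose (14 adjusted over the list alone; camera adjusted p 7.2e-23, adjusted p 0.0021 with an estimated correlation). Among 9 flowering-time genes FT, FLC (2.42, SE 0.35) and SOC1 (0.57, SE 0.14) rose (3 higher and 2 lower adjusted over the list alone; camera adjusted p 0.16). CHLI1 and PORC were lower among 22 chlorophyll and heme genes (2 lower and 1 higher adjusted over the list alone; camera adjusted p 0.030, adjusted p = 0.20 with an estimated correlation). SAPX and AT1G20620, a catalase gene, were higher in the oxidative stress list of 15 (3 adjusted over the list alone; camera adjusted p 0.10). In the defence list of 17, PBS3 was higher and EDS1 and ICS1, of salicylic acid signalling and synthesis, lower (1 and 2 adjusted over the list alone; camera adjusted p 0.28). KAT1, a guard cell potassium channel, and SEOR1 were lower and SPT, of carpel growth, and PRR9 were higher, each the member called in its list (1, 1, 1 and 0 adjusted over the list alone). With a library left out, COBL9 lost its call in 11 of the 12 fits (edgeR adjusted p up to 0.14), SOC1 in 10 (0.16), CHLI1 and SEOR1 in 9 (0.16 and 0.12) and PRR9 in 8 (0.12). AT1G20620 and KAT1 lost it in 4 (0.12 and 0.054), EDS1 in 3 (0.080) and PORC and ICS1 in 1 (0.063 and 0.056).

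Other large increases were AT5G60140 (at least 160-fold), SCPL43 (at least 144-fold), AT5G39220, a hydrolase gene (log2 fold change 7.61, SE 0.71), the homeobox genes HB40 (7.14, SE 0.56), ATHB54 (6.73, SE 0.48) and AT2G18550 (6.72, SE 0.38), and SWEET10 (6.83, SE 0.46). The largest decreases were AT3G16670 (-5.06, SE 0.83), ACS4, of ethylene synthesis (-4.54, SE 0.69), AT3G05730 (-3.76, SE 0.35), and GH9C1, an endoglucanase of root hairs (-3.47, SE 0.74). Others were CRK12 (-3.36, SE 0.34), SESA5 (-3.20, SE 0.70), AT4G25090 (-2.88, SE 0.57), AT1G07500 (-2.83, SE 0.62), the lectin gene AT5G03350, from 152 ± 23.5 to 22.9 ± 9.63 CPM (-2.73, SE 0.28), and MAM3, of glucosinolate chain elongation (-2.64, SE 0.43). GH9C1, SESA5, AT4G25090 and AT1G07500 lost their calls with some library left out. The numbers higher and lower went to 444 and 245 without replicate 3 of deficient wild type, 358 and 146 without replicate 1 and 375 and 138 without replicate 2 of deficient clf. Without replicate 1 of deficient wild type 224 were lower. The share of calls that were higher was 62.0%, against 74.7% by limma on FPKM (830 higher, 281 lower) and 53.1% with a term for the 4 libraries that stood apart (1670 higher, 1476 lower).

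The clf effects at both iron levels shared 514 called genes, each in the same direction, where independent lists would share 33.8, and the log2 fold changes of all genes correlated with r = 0.67 across genes. The shared number was 289 without replicate 2 of sufficient clf and 1334 with a term for the 4 libraries that stood apart. Of the genes called for the mean iron effect (2608) and the mean clf effect (2432), 262 moved in the same and 323 in opposite directions, against 167 and 165 for independent lists (r = 0.05 across genes). The excess of opposite directions turned under other settings: 1030 moved in the same and 883 in opposite directions with a term for the 4 libraries that stood apart, 878 and 740 without them, and 458 and 293 without replicate 3 of deficient clf. The iron effect in wild type and the clf effect on sufficient iron share the sufficient wild-type libraries. They had 180 genes in common in the same direction and 28 in opposite directions, against 43.1 and 42.7 for independent lists. In 20 simulations without effects 0 to 1 genes were shared in the same direction. Groups without effects leave few genes to call, so this simulated count is no chance level for lists of this size. The 180 became 55 without replicate 2 of sufficient clf and 943 with a term for the 4 libraries that stood apart. Their covariance was 0.180 against 0.106 simulated, a difference of 0.0745 (r = 0.31 against 0.51 simulated). With 3 control libraries no split leaves 2 in each part, so part of the excess may come from the shared controls.

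The interaction asks whether the iron response differs between the genotypes. ERD5 (AT3G30775, chromosome 3, 12448636 to 12451556), for proline dehydrogenase, which breaks down proline, fell in wild type from 317 ± 37.2 to 63.0 ± 8.22 CPM and was at 310 ± 40.7 and 322 ± 33.4 CPM in clf. Its interaction log2 fold change was 2.39 (SE 0.20, edgeR adjusted p 0.0036), and the call held with any of the 12 libraries left out. It was the 1 gene called, with 0 lower by edgeR, against 56 higher and 38 lower by DESeq2 and 1416 genes at an unadjusted p under 0.05. The next genes by p did not pass. They were AT1G80440, a kelch repeat gene (1.05, SE 0.13, edgeR adjusted p 0.085), AT3G48390, an MA3 domain gene (1.72, SE 0.23, 0.092), GRP3S, a glycine-rich protein gene (1.02, SE 0.14, 0.096), and AT1G67750, a pectate lyase gene (-1.88, SE 0.28, 0.16). HB33, SIP2, AT1G03990, AT3G22235 and AT3G11000 followed at an edgeR adjusted p of 0.18. Without replicate 3 of sufficient wild type 3 genes were higher, and with a term for the 4 libraries that stood apart 55 were higher and 42 lower.

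**Figure D5:**
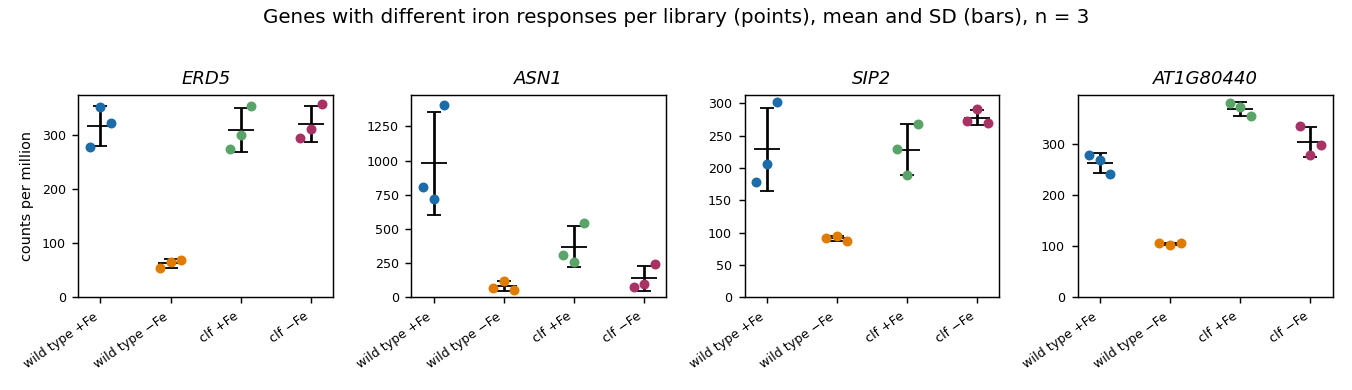
The vertical axis of each panel gives CPM from 0, with points for the 3 libraries of each of the 4 groups and bars for the group mean and SD. ERD5 was at 63.0 CPM in wild type on deficient iron and between 310 and 322 CPM on average in the 2 clf groups, and SIP2 at 91.5 CPM in wild type and 278 CPM in clf on deficient iron.

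By camera, 7 lists differed in their iron response between genotypes, none with an estimated correlation. Genes of iron storage and iron-containing proteins changed by 1.40 on the log2 scale more positively in clf (median of 10). Their camera adjusted p was 1.9e-05 (adjusted p = 0.18 with an estimated correlation, 5 members adjusted over the list alone). Members include FSD1 (1.46, SE 0.28, edgeR adjusted p 0.25) and NEET (2.34, SE 0.42, edgeR adjusted p 0.20). Signalling genes had a median of -0.59 (camera adjusted p 0.0070, adjusted p = 0.18 with an estimated correlation), photosystem genes 0.22 (1.9e-05 and 0.63) and chlorophyll and heme genes 0.16 (0.025 and 0.18). Root markers, with -1.63 (3.0e-05 and 0.47), moved beside these, as did anthocyanin genes with -3.87 (1.5e-05 and 0.31; 5 lower adjusted over the list alone) and glucosinolate genes with -0.30 (0.025 and 0.59). In each of the 7 lists 0 members passed over all genes by edgeR, with 1 to 7 at an unadjusted p under 0.05 and up to 3 by DESeq2.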

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

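Of the tests weighed here, those on time of day, on the root and leaf markers and without the libraries that stood apart were chosen after the result was seen. For those on depth and on splits the prediction was written before the test, but thinning was itself added after seeing the data. The results in this part were picked because a test, or the direction of all libraries, set the iron response apart between the genotypes. ERD5 had an interaction of 2.39 on the log2 scale. Medians of the lists called by camera were -0.59 for iron signalling, 1.40 for iron storage and iron-containing proteins, 0.22 for photosystems and 0.16 for chlorophyll and heme. They were -1.63 for root markers, -3.87 for anthocyanin and flavonoids and -0.30 for aliphatic glucosinolates. None of these 7 lists passed with an estimated correlation (adjusted p = 0.18, 0.18, 0.63, 0.18, 0.47, 0.31 and 0.59 in this order). In AT1G75490 (2.34) and SIP2 (1.61) all libraries moved down with deficiency in wild type and up in clf. They were picked by direction alone, and edgeR's interaction test did not call them (adjusted p 0.33 for AT1G75490 and 0.18 for SIP2). With the term for the 4 libraries that stood apart, chosen after seeing the data, the edgeR adjusted p was 0.044 and 0.013, and without these libraries 0.082 and 0.0073. Both fits lower the spread tested against by that choice, so these p-values may be too small. In all, 72 genes had such opposite movements, against 95.7 from chance non-overlap if no gene responded to iron. Since many genes responded alike in both genotypes, the 95.7 is no fitting chance level. The movement alone is therefore given no weight.

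In each group 1 library stood apart, along a component with 56.3% of the variance within groups. The same library had the highest PRR5, TOC1, GI and FKF1 and the lowest CCA1 and LHY in 4 of 4 groups, which is consistent with harvest at another time of day (TOC1 2.95 to 5.33 times the other 2). Without the 20 genes of the clock list the component held 56.2% of the variance, and the same 4 libraries stood apart. So few of the 19148 genes could hardly change it, so this does not decide whether the component follows the clock. The oxidative stress list had a mean log2 CPM of 5.20 and 5.15 in that library of sufficient and deficient wild type. In sufficient clf it had 5.28 there. The other libraries of these groups had 2.98 to 4.27. In deficient clf the library that stood apart had 4.32, against 4.40 and 4.12. Less root tissue is argued against for the higher TOC1 only. A loss of root RNA can raise no transcript by more than those of the shoot alone, while the TOC1 ratio was at least 3.31 times that of the leaf markers. For the lower root markers, at 0.422 to 0.505 of the other 2 in 4 of 4 groups, less root tissue stays open beside the time of day. Depth is argued against, since the same library stood apart in 4 of 4 groups after thinning. No harvest time is given in the sources used here, and no biological explanation was tested.

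The iron response was smaller in clf over the 2608 genes of the mean iron effect, with a signed median difference of -0.22. After thinning every library to the smallest total the difference was -0.22 as well. Thinning keeps each gene's expected share of reads, so a large shift was unlikely. The test therefore says little on deeper sequencing of the deficient libraries. The libraries that stood apart are argued against as the whole cause, with -0.21 without them on the 2606 genes of the same set still tested. On the 4563 genes called anew without them it was -0.154, barely past a bound of -0.15 written after the result was seen. The fry p of 0.00061 there may be too small, since leaving out the libraries farthest out lowers the spread. In 3 of 100 splits, which keep every iron label and include the real one, the difference was as low, the lowest of the others at -0.26. Exchanging the genotype labels of a split turns its sign, yet only negative differences were counted and no split was drawn together with its mirror. A count by absolute size was not made, so these splits do not decide whether the grouping by genotype is unusual. The data are in line with a weaker iron response in clf, which could come from less severe deficiency as well as from altered regulation, and no measured iron content is used here to tell these apart.

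Some genes of iron acquisition, best known from roots, rose in these shoots: edgeR called 7 of 13 in wild type and 2 in clf. As a list they did not pass with an estimated correlation (adjusted p = 0.13 in each, and 0.098 for the mean iron effect). Over both genotypes the acquisition score rose by 1.71 and the root marker score changed by -0.23, a difference of 1.93 (exact permutation p 0.01 over 400 arrangements), but the root markers went in opposite directions. In clf the acquisition score was 1.62 higher and the root marker score 0.92 lower, a difference of 2.54. More root tissue is argued against there, since acquisition minus root score was 2.78 to 3.57 in the deficient and -0.50 to 1.67 in the sufficient libraries. In wild type both were higher on deficient iron, by 1.79 and 0.47, a difference of 1.32. More root tissue stays open as a part there, since the libraries overlapped (2.21 to 3.32 and 0.47 to 2.63). A constant small share of root RNA that responds stays open: within groups the root marker and acquisition scores had r = 0.0518 over 12 libraries (permutation p 0.90, 1296 arrangements; rho = -0.12, p 0.73). No biological explanation was tested.

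In other splits of the libraries, each of the 4 simple comparisons had 1 of 10 splits with a count as large (the real split), with 670, 113, 550 and 619 genes in a fit of its own groups and 0 as the highest other count. With 10 splits no share under 0.05 can be reached, so this does not decide. The mean iron effect had 1 of 100 (2608 genes, highest other 1300) and the mean clf effect 1 of 100 (2432, highest other 417). The interaction had 11 of 100 with at least its 1 gene and up to 1300. In 9 of these 11 the genotypes keep unequal numbers of iron labels, which carries the iron effect into the interaction, so these splits do not decide whether its count exceeds chance. The split with 1300 keeps the iron labels of all wild-type libraries.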

How the results depend on the processing

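With each library left out, 5059 results of named genes kept their side of the threshold, 372 lost it, 17 gained it and 0 reversed. Direction was compared only where the main fit or the fit with a library left out called the gene. DESeq2 size factors, no filter and a strict filter kept every count of called genes per comparison and overlap within 1.5 times, and so did the replicate block (960 higher and 870 lower for iron in wild type, 108 and 133 for iron in clf, 682 and 283 for clf on sufficient and 715 and 474 on deficient iron, 1 and 0 for the interaction). Of 52 counts of called list members, these 4 settings moved 2, 5, 8 and 11 by more. Under the replicate block 16 results of named genes lost their call and 4 gained it. Without a filter 9 lost it and 445 kept their side of the threshold. With the strict filter 2 gained it and 408 kept their side, and results of genes below that filter were not tested. With DESeq2 size factors 1 lost and 1 gained it. The replicate numbers as given do not pair the libraries: 12 of 18 same-number pairs had r over 0.1 (-0.63 to 0.64) and 4 of 12 libraries correlated best with their own number. If numbers 2 and 3 of deficient wild type were exchanged, the library that stood apart would be number 3 in each group (r 0.37 to 0.72 among these 4). Exchanged numbers stay open, and of the fits only the block depends on them. Counts below are higher and lower genes in this order: iron in wild type, iron in clf, clf on sufficient iron, clf on deficient iron, interaction. The cause of each move was not tested, except where fewer libraries, a higher threshold or the scaling of FPKM given below make it.

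The DESeq2 Wald test gave 1280 and 1324, 482 and 439, 1034 and 610, 1161 and 817, 56 and 38. Only the groups compared gave 273 and 397, 60 and 53, 427 and 123, 404 and 215, with 7 lists called for clf on deficient iron. A log2 fold change of at least 1 gave 353 and 309, 88 and 69, 479 and 90, 482 and 163. Limma on FPKM gave 2633 and 462, 472 and 120, 1016 and 144, 830 and 281. FPKM carry no TMM factors, which were 0.924, 0.919 and 0.832 in sufficient and 1.05, 1.03 and 1.08 in deficient wild type. Leaving these factors out raises every log2 fold change for iron in wild type, and with it the share of higher genes. Camera with an estimated correlation called 3, 3, 2, 1 and 0 lists. Chosen after seeing the data, a term for the 4 libraries that stood apart gave 2165 and 1950, 938 and 803, 1649 and 1099, 1670 and 1476, 55 and 42. Its overlaps were 1030 genes in the same and 883 in opposite directions for the mean effects, 943 for iron in wild type with clf on sufficient iron, 1209 for both iron effects and 1334 for both clf effects. Leaving these 4 out gave 1759 and 1471, 950 and 710, 1185 and 773, 1754 and 1466, 66 and 31, with overlaps of 878, 740, 592, 982 and 1159. Thinning to the smallest library gave 3 higher genes for the interaction and 2 lists for clf on deficient iron.

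With each library left out, counts ranged over 372 to 973 higher and 476 to 955 lower, 46 to 265 and 44 to 188, 307 to 723 and 79 to 293, 358 to 905 and 138 to 651, and 1 to 3 higher for the interaction. The overlaps ranged over 112 to 458, 165 to 311, 55 to 213, 78 to 319 and 289 to 544, in the order above, and 2 to 8 lists were called for clf on deficient iron. Genes near 0 counts in a group are limited by depth to bounds or wide intervals.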

Other observations

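The genes of this part and the fits behind them were chosen after the results were seen. With a term for the 4 libraries that stood apart, 55 genes were higher and 42 lower in the interaction, and without these libraries 66 and 31. Of these, 46 were in both, each in the same direction. The 2 fits share the remaining libraries and the same choice, so this shared direction is no separate support. That choice lowers the spread tested against, so the adjusted p-values of both fits may be too small. Adjusted p-values here are edgeR's with that term, and without it only ERD5 of the genes below was called in the interaction (edgeR adjusted p 0.0036). The genes of this paragraph fell on deficient iron in wild type and were not called for iron in clf by the edgeR test without the term. Besides ERD5 (2.39, SE 0.17, adjusted p 0.00028), ASN1 was at 979 ± 375 and 82.7 ± 35.3 CPM in wild type and 370 ± 150 and 139 ± 92.3 CPM in clf (interaction 2.07, SE 0.21, adjusted p 0.0079). AT3G15450 went from 687 ± 286 to 157 ± 120 CPM in wild type and was at 586 ± 294 and 518 ± 268 CPM in clf (2.11, SE 0.24, adjusted p 0.0099). SIP2, of raffinose breakdown, was at 229 ± 64.7 and 91.5 ± 4.06 CPM in wild type and 229 ± 39.0 and 278 ± 11.2 CPM in clf (1.60, SE 0.20, adjusted p 0.013). STP1, a hexose transporter, was at 997 ± 378 and 236 ± 107 CPM in wild type and 656 ± 281 and 380 ± 255 CPM in clf (1.22, SE 0.18, adjusted p 0.022). TPS11, a trehalose phosphate synthase family gene, was at 362 ± 105 and 105 ± 20.1 CPM in wild type and 269 ± 50.3 and 193 ± 64.2 CPM in clf (1.24, SE 0.18, adjusted p 0.016), and was not called without the 4 libraries (adjusted p 0.058). Without the term, the interaction's edgeR adjusted p was 0.53 for ASN1, 0.64 for AT3G15450, 0.18 for SIP2, 0.73 for STP1 and 0.50 for TPS11.

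In the other direction, MIPS2, of inositol synthesis, was at 97.7 ± 27.4 and 285 ± 126 CPM in wild type and 106 ± 27.5 and 73.9 ± 19.0 CPM in clf (-2.05, SE 0.24, adjusted p 0.0099). SAG29, a sugar transporter of senescence, was at 3.17 ± 0.686 and 69.5 ± 25.5 CPM in wild type and 6.41 ± 3.23 and 19.6 ± 1.64 CPM in clf (-2.76, SE 0.38, adjusted p 0.015). CGLD27, a plastid protein gene of the iron response, was at 44.9 ± 12.2 and 451 ± 35.6 CPM in wild type and 66.3 ± 10.9 and 308 ± 34.9 CPM in clf (-1.14, SE 0.15, adjusted p 0.015). FSD1 was among the genes called with the term (1.44, SE 0.22, adjusted p 0.022). Without the term, the edgeR adjusted p was 0.39 for MIPS2, 0.20 for SAG29, 0.425 for CGLD27 and 0.25 for FSD1. SESA5 had 0 CPM in all 6 sufficient libraries, 18.3, 17.4 and 14.2 CPM in the deficient wild-type libraries and 0.764, 0.660 and 3.93 CPM in those of clf.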
